A study of Saccharomyces cerevisiae with 67 samples.

How the data were processed

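The series measured contacts of DNA around a site-specific DSB on chromosome V of budding yeast. Per the labels' protocols, cells grown in lactate medium were held in G1 with alpha-factor and released into galactose, which induces the nuclease. IAA was added at release for Scc1-AID, and doxycycline with IAA 1 h after release for Pol3 and Rfc1. Cells were fixed with formaldehyde and EGS, oligonucleotides were annealed to the ssDNA, and Hi-C libraries were captured in 2 rounds. Of 67 samples, 36 ssHi-C libraries were analysed and the Hi-C libraries were not used here. Some of the 36 libraries and comparisons, which entered the fit, its filter and the p adjustments, are not reported here.

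The deposited matrices hold raw counts of contacts between pairs of 74961 restriction fragments, with no normalization by the authors. Their names carry a tag of 20 (12 libraries) or 30 (24 libraries), read here as a mapping-quality setting. Deposited tables for 34 of the libraries give, for each of 30 capture probes, the fraction of its contacts that falls in each 1 kb bin, and the authors' averages over several probes are fractions too. The build is R64 plus an artificial chromosome, per the labels, and the aligner and its version are not given in the sources used here. The 1 kb tables carry positions and the matrices only fragment numbers, so fragments were placed by matching the tables with the counts. Of the probe columns 1006 were used, 6 did not match and 8 were empty. Of 12181 bin boundaries 11745 (96.4%) fell in 1 fragment, and 99.4% of contacts fell in the same 10 kb window as in the deposited tables. Positions on chromosome V to the right of the break run about 2 kb ahead of R64, so gene names of windows there can be off by that much. Gene names and the positions of loci come from the R64 annotation.

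Probe sets were taken from the authors' averages: 6 left and 5 right ssDNA probes, 11 control probes elsewhere, and 8 probes near the break in no average and not used in the measures. The break was placed from the distances in the headers. Contacts within 10 kb of it were left out, so URA3, which lies there, has no value. The trans share is the percent of ssDNA contacts on the other 15 chromosomes. The donor share and the shares of the RE, HML, HMR, MAT and GAL genes are contacts within 5 kb of the locus as percent of trans contacts, and the rDNA share uses flanks of 20 kb. Enrichments are contact densities within 20 kb of centromeres or chromosome ends over those of the rest of the arms. Of 600 bins near ends 551 (91.8%) hold a fragment, against 593 of 600 (98.8%) near centromeres and 10260 of 10302 (99.6%) elsewhere, so subtelomeric enrichment is understated alike in all libraries. Control probes gave, on average over the 31 libraries reported, a trans share of 98.9%, a donor share of 0.0321%, a pericentromeric enrichment of 2.19 and a subtelomeric enrichment of 0.133. These probes lie on chromosomes II, IV, VIII, X and XV, and all contacts off chromosome V counted as trans for them. Contacts with their own chromosomes are thus included, and the values are not like measures to those of ssDNA probes. Probe yields are contacts per 10000 control-probe contacts.

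Counts of the ssDNA probes in 10 kb windows were fitted with edgeR 4.0.16 (quasi-likelihood test, limma 3.58.1, R 4.3.3) over the 14 libraries of the 6 replicated groups. Windows were kept by filterByExpr, which left 1089, and library size was the total over them. The common dispersion was 0.0866, a coefficient of variation of 0.294. Windows with a Benjamini-Hochberg adjusted p below 0.05 were called. Sets of windows were tested with camera at a preset correlation of 0.01: near centromeres, near ends, arm middles, tRNA genes, GAL genes, mating-type loci with the RE, rDNA flanks, and chromosome V within 100 kb of the break. Group means of measures were compared by exact two-sided permutation tests (scipy 1.17.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3), with Benjamini-Hochberg adjustment over 20 planned values. Conditions with 1 library have 95% intervals, Wilson for shares and exact binomial for enrichments, and a floor of 3 counts.

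Windows are named by a rule set before the data were examined: the 10 with the largest log2 change in each direction among those called whose libraries do not overlap between the groups, with up to 3 genes each, longest first. Fixed loci are named whatever their values: LYS2, the RE, HML, HMR, MAT, URA3, the 16 centromeres, GAL1-GAL10-GAL7, GAL2 and the rDNA. Their windows are those that overlap the locus, and the centromeres are given as a range over their windows.

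The fit was tested on simulated counts with the groups and depths of each comparison. Every window was drawn with the common dispersion and without repeated pairs of fragments, and the percents cover simulated windows that passed the filter. Detection in the data can thus be lower than these percents. Of windows simulated 4-fold higher and lower, 94% and 83.3% were found for WT 4 h against 2 h and 64% and 59.6% for Cdc45. Of those simulated 2-fold, 16.3% and 26% were found for WT, and 12.2% and 8.70% for Cdc45. False calls made up 3.57% (WT) and 4.11% (Cdc45) of calls, and none had the wrong sign. Simulated values of 70 for the trans share, 3 for pericentromeric and 0.5 for subtelomeric enrichment were recovered as 69.96, 2.96 and 0.463.

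Alternatives were TMM scaling, trans contacts as library size, DESeq2 1.42.0, no filter, 20 kb windows, other zones around the break, left or right probes alone, other flanks, per-probe means, division by control probes, chromosome XII left out, the tag as covariate, the replicate number as a block, a fit of the 2 groups alone, and each library left out. Counting each pair of fragments once, and leaving chromosome III out of the subtelomeric values, were added after the data were seen. So was counting each pair once with the library and its WT libraries drawn down to the contacts of the shallowest (mean of 100 draws), since the trans share of distinct pairs rises with depth.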

Results

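Contacts of single-stranded DNA (ssDNA) with the rest of the genome were measured in budding yeast after a site-specific double-strand break (DSB) on chromosome V. The assay, ssHi-C, is Hi-C with short oligonucleotides annealed to ssDNA so that restriction sites are double-stranded and can be cut, followed by capture of chosen fragments. Of the 67 samples of the series, results of 31 ssHi-C libraries are given here. The replicated groups were wild type (WT) at 2 h (n = 2) and 4 h (n = 4) after galactose induction of the break and Cdc45-AID at 4 h with DMSO (n = 2) or IAA (n = 2). Each of the other 21 conditions had 1 library, so its values carry a 95% counting interval and no test. Libraries held 3046065 to 19407042 contacts, of which 1222 to 114391 joined an ssDNA probe on either side of the break to nuclear DNA outside a zone of 10 kb around the break. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, and intervals cover counting error only.

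Genotype labels were checked first, from contacts of the deleted sequences. EXO1 (chromosome XV), the gene of a resection nuclease, had 0 contacts in both exo1D libraries and 886 to 6166 in the other 29. The element called RE in the labels was taken to lie between KAR4 and SPB1 on the left arm of chromosome III. There 5 fragments had 5 contacts in the RE-deleted library and 465 to 3519 in the other 30. These fragments were picked for having few contacts in the RE-deleted library, so this contrast is no independent check of that label. The protein depletions (Scc1, Cdc45, Pol3, Rfc1) and the missing donor left no such trace and were not checked.

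Probe signal depended on the annealing oligonucleotides and on the break. With left-side oligonucleotides alone the 6 left probes yielded a median of 83.9% of the WT 4 h mean, relative to control-probe contacts, and the 5 right probes 0.102%. The right-side set gave the opposite, 76.0% at right probes and 3.50% at left probes. Without a break the medians were 4.93% on the left and 2.35% on the right, although the right probe closest to the break, at 120.2 kb, kept 36.0%. In that library ssDNA probes gave 1.08 contacts per 100 control contacts, against 29.8 ± 7.49 (SD, n = 4) in WT at 4 h.

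**Figure D1:**
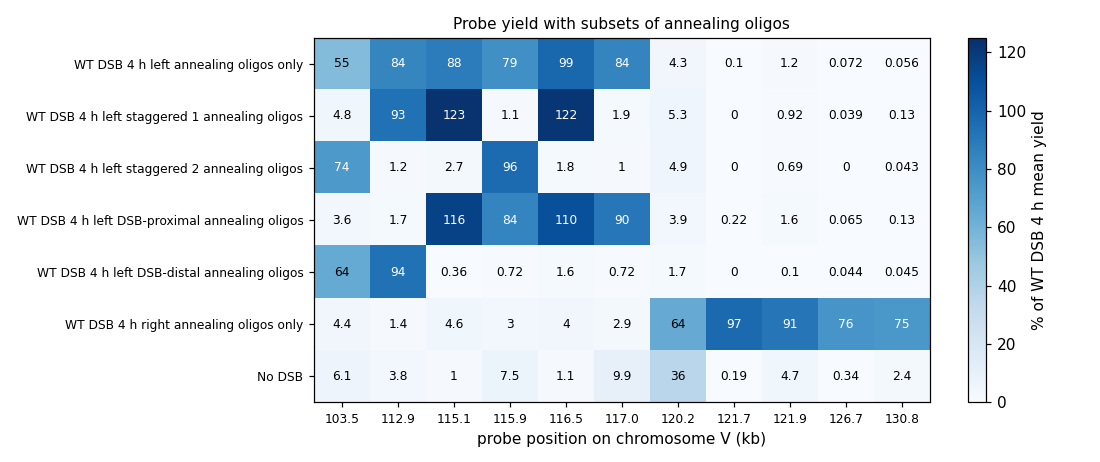
Yield of each ssDNA probe (columns, position on chromosome V in kb) in 6 WT libraries made with subsets of the annealing oligonucleotides and in the library without a break (1 library per line), as percent of the WT 4 h mean yield relative to control-probe contacts. The left-only set gives a median of 83.9% at left probes and 0.102% at right probes, and the right-side set gives a median of 76.0% at right probes.

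The comparison of WT at 4 h with 2 h asks how ssDNA contacts change as resection and homology search proceed. Contacts with the mating-type loci and the RE, on both arms of chromosome III, were fewer at 4 h than at 2 h. At 2 h the RE region took 4.90% and 1.17% of trans contacts in the 2 libraries and all of chromosome III 20.9% and 8.71%. At 4 h the RE region took 0.691% ± 0.538 (SD, n = 4) and chromosome III 6.07% ± 2.04, with overlapping libraries in both measures (exact two-sided permutation test, p = 0.267). Windows of 10 kb at HML, the silent mating-type cassette on the left arm, at the RE and at HMR, the right-arm cassette, had log2 changes of −2.01, −2.02 and −1.80 (SE 0.444, 0.487 and 0.443), and the other RE window, on the KAR4 side, −1.89. With each pair counted once, an alternative chosen after the data were seen, the 4 changes shrank to −1.21, −1.44, −1.35 and −1.08 but passed edgeR (adjusted p at most 4.1e-05). The median window moved by 0.20, and relative to it the HML and RE changes were −2.21 and −2.22. In the planned fit none of the 1089 windows passed edgeR at an adjusted p of 0.05 (lowest 0.0831), while 60 had an unadjusted p below 0.05 and DESeq2 called 9, TMM scaling 9 and trans contacts as library size 6, all lower. The set of 6 windows at mating-type loci and the RE fell by the camera set test (adjusted p = 3e-13, and adjusted p = 0.0369 with an estimated correlation), and 4 of the 6 were lower when adjusted over the list alone. Without WT 4 h replicate 2 edgeR called 10 windows, without WT 2 h replicate 2 it called 9, and without any of the other 4 libraries 0. WT 2 h replicate 2 lies within the 4 h range at the RE (0.251% to 1.43%) and over chromosome III (4.58% to 9.06%), so the fall rests largely on WT 2 h replicate 1. Subtelomeric windows also fell as a set (adjusted p = 0.00207, and adjusted p = 0.0452 with an estimated correlation; 4 of 30 lower when adjusted over the list alone), and their median was −0.25 relative to all windows. All 4 of these windows lie on chromosome III, and the 26 subtelomeric windows of the other chromosomes did not fall as a set (adjusted p = 0.451), an alternative chosen after the data were seen. Chromosome V windows within 100 kb of the break fell as a set too (adjusted p = 1.3e-05, and adjusted p = 0.0529 with an estimated correlation), with a median of −0.18 and 2 of 19 lower when adjusted over the list alone. The sets of GAL genes and of the rDNA flanks did not pass the set test (adjusted p = 0.541 and 0.226), nor did the pericentromeric set (adjusted p = 0.0531). The windows at the mating-type locus MAT changed by −0.28 and −0.42 and at GAL1-GAL10-GAL7 by 0.07 and 0.55. The GAL2 window (chromosome XII) changed by 1.14 and the windows that overlap the rDNA itself by 2.03 and 0.64. None of these was called. The GAL2 share of trans contacts was 0.102% ± 0.0310 at 4 h and 0.0536% ± 0.00150 at 2 h, without overlap (exact two-sided permutation test, p = 0.133). The windows of the 16 centromeres ran from −0.18 (chromosome V) to 1.10 (chromosome IX), none called.

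Distal probes gave more signal at 4 h in WT. Per 10000 control contacts, the left probe at 103.5 kb, 15.5 kb from the break, yielded 10.98 ± 0.200 (SD, n = 2) at 2 h and 177 ± 86.5 (n = 4) at 4 h. The right probe at 130.8 kb yielded 26.1 ± 11.4 and 431 ± 88.0, while the probe at 116.5 kb, 2.46 kb from the break, gave 265 ± 43.5 and 228 ± 15.9. Both distal probes were higher in all 4 libraries at 4 h than in both at 2 h (exact two-sided permutation test, p = 0.133, the smallest 4 against 2 allow). The trans share was 65.9% ± 3.58 at 2 h and 70.1% ± 1.98 at 4 h, and the donor share, contacts within 5 kb of LYS2 (the donor locus, chromosome II) among trans contacts, was 0.275% ± 0.0431 and 0.315% ± 0.106. Of the 14 fragments at LYS2 11 had 0 contacts in every library, so this share rests on the flanks of the gene. The windows that hold LYS2 changed by 0.29 and 0.36 on the log2 scale (edgeR, adjusted p = 0.971 in both). Pericentromeric enrichment, the contact density within 20 kb of the other 15 centromeres over that of chromosome arms, was 2.05 ± 0.168 and 2.38 ± 0.360. None of the 3 measures separated the times (exact two-sided permutation test, p = 0.267, 0.800 and 0.267), whereas subtelomeric enrichment did, at 0.681 ± 0.0495 at 4 h and 1.08 ± 0.360 at 2 h (p = 0.133, the difference running from −0.653 to −0.144 with 1 library left out, or 0.444 after Benjamini-Hochberg adjustment over the 20 values planned). Without chromosome III the means were 0.598 and 0.657. A further 75 values were compared without adjustment. Libraries carried a tag of 30 or 20, read here as mapping quality. All libraries of the replicated groups carried tag 30 except WT 4 h replicate 4, which carried tag 20. Tag 20 was also that of the Scc1-depleted, no-donor, Pol3-depleted, Pol3/Rfc1-depleted and both RE-strain libraries. Each of these is thus set against WT libraries that at 2 h all carried tag 30 and at 4 h mostly did. The tag was not separated from the genotype there. The labels also list IAA for the Scc1-, Pol3- and Pol3/Rfc1-depleted libraries, and doxycycline for those of Pol3 and Pol3/Rfc1. They list neither drug for WT, so drug and depletion were not separated.

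**Figure D2:**
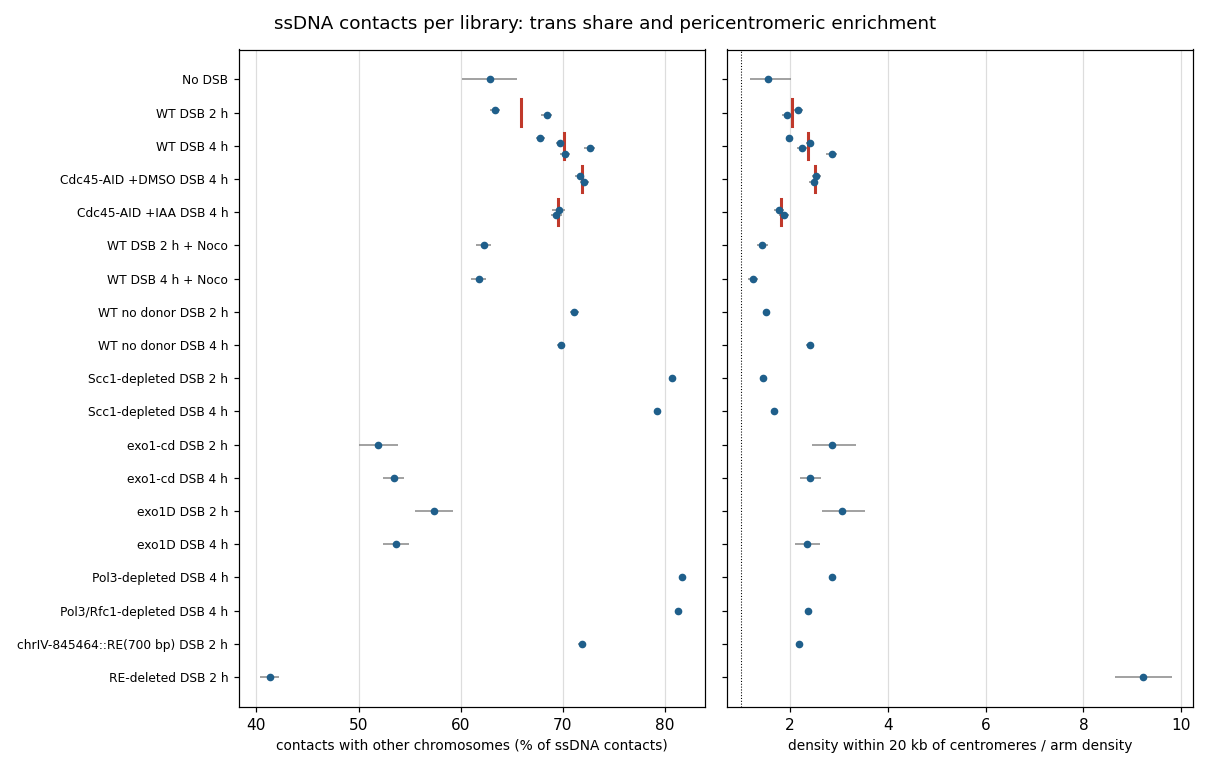
Trans share (left, percent of ssDNA contacts) and pericentromeric enrichment (right, density ratio, dotted line at 1) per library (points, with 95% counting intervals) and group means (bars) of 19 conditions with the full oligonucleotide set. At 4 h the WT mean was 70.1% and 2.38, and the RE-deleted library had the lowest trans share (41.3%) and the highest enrichment (9.21).

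Cdc45 is a subunit of the replicative helicase, and its degron strain was compared with and without IAA, which triggers degradation, after release from G1. IAA libraries had a lower pericentromeric enrichment and a lower RE share, and no single window was called at either place. Pericentromeric enrichment was 1.83 ± 0.0716 with IAA and 2.52 ± 0.0398 with DMSO (SD, n = 2), subtelomeric enrichment 0.593 ± 0.0212 and 0.717 ± 0.0180 (0.577 and 0.632 without chromosome III), and the RE region took 0.147% ± 0.00104 and 0.324% ± 0.0171 of trans contacts. The share at GAL1-GAL10-GAL7, the galactose-induced genes of chromosome II, was 0.124% ± 0.0311 and 0.391% ± 0.184, while at GAL2 it was higher with IAA, 0.0916% ± 0.0311 against 0.0401% ± 0.0000160. The distal probe at 103.5 kb yielded 106 ± 43.5 with IAA and 207 ± 58.8 with DMSO per 10000 control contacts. These values did not overlap (exact two-sided permutation test, p = 0.333, the smallest possible). The trans share was 69.5% ± 0.164 and 71.9% ± 0.340, a difference of −2.39 points that was 1.44 with left-side probes alone, and the donor share 0.251% ± 0.0184 and 0.270% ± 0.0254. The LYS2 windows changed by −0.01 and −0.10 on the log2 scale (edgeR, adjusted p = 0.999 and 0.966) and the GAL1-GAL10-GAL7 windows by −1.73 and −0.99 (adjusted p = 0.409 and 0.724). At GAL2 the window changed by 0.88, at HML by −0.64, at HMR by −0.63 and at the RE by −0.91 and −1.13. The MAT windows changed by 0.32 and −0.27 and those that overlap the rDNA itself by −0.23 and −0.06. The centromere windows ran from −1.32 (chromosome VI) to 0.56 (chromosome V, the only rise). No window passed edgeR or DESeq2, 74 had an unadjusted p below 0.05, and 71 in DESeq2. Leaving out 1 library, edgeR called 4 windows without IAA replicate 1, 2 without IAA replicate 2 and 1 without DMSO replicate 2. Pericentromeric windows fell as a set (camera, adjusted p = 4.6e-09, and adjusted p = 0.0970 with an estimated correlation), with a median of −0.47. Arm windows rose as a set with a median of 0.01 (adjusted p = 0.0159, and adjusted p = 0.502 with an estimated correlation). The mating-type and RE set (adjusted p = 0.105, and adjusted p = 0.529 with an estimated correlation) and the GAL set (adjusted p = 0.499) did not pass.

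Scc1, a cohesin subunit, was depleted with IAA from release to ask how cohesin shapes these contacts. Depleted libraries had trans shares of 80.7% (Wilson interval 80.4 to 81.1) at 2 h and 79.3% (78.9 to 79.6) at 4 h, above the highest WT library of each time (68.4% and 72.6%). The differences from the WT means, 14.8 and 9.16 points, were 7.88 and 3.70 with each pair counted once. That share rises with depth, and with the libraries also drawn down to equal depth the differences were 7.01 and 3.13, an alternative chosen after the data were seen. Pericentromeric enrichment was 1.44 and 1.68, below every WT library, and chromosome III took 7.37% at 2 h, below both WT libraries, and 5.13% at 4 h, within the WT range. The donor share was 0.319% (0.272 to 0.374) at 2 h, with an interval that reaches the higher WT library (0.244% and 0.305%), and its difference from WT changed sign with right-side probes (−0.0231 points) and when divided by the control-probe value (−0.0988). At 4 h it was 0.336%, within the WT range. The RE region held 0.759% at 2 h, below both WT libraries, and 0.265% at 4 h, within the WT range.

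In WT cells labelled Noco, an abbreviation the labels do not explain, pericentromeric enrichment was 1.44 (1.33 to 1.55) at 2 h and 1.24 (1.15 to 1.34) at 4 h, below every WT library of the same time. Its differences from WT at 2 h and 4 h were −0.412 and −0.225 from left-side probes and −1.69 and −2.64 from right-side probes. The trans shares of 62.3% and 61.7% were also below WT. At LYS2 the shares were 0.470% (0.356 to 0.621) and 1.48% (1.28 to 1.72), above WT, and the 4 h value was 0.545% with each pair counted once. The difference at 4 h came mostly from right-side probes (3.09 points, against 0.230 from left-side probes), and at 2 h it was −0.000513 when divided by the control-probe value. The RE share was 0.979% at 2 h and 0.123% at 4 h, below the WT libraries of each time.

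The no-donor WT libraries had trans shares of 71.1% and 69.8%, the first above both WT libraries at 2 h and the second within the WT range at 4 h. The difference at 2 h was 8.26 points from left-side probes and −2.13 from right-side probes. With each pair counted once at equal depth it was 2.87 points. Pericentromeric enrichment was 1.52 (1.46 to 1.58) at 2 h, below both WT libraries, and 2.41 at 4 h, within the WT range. The difference at 2 h changed sign when divided by the control-probe value (0.481). That value includes contacts of control probes with the centromeres of their own chromosomes, so the division cannot decide about ssDNA contacts. Contacts near LYS2 were 0.0613% (0.0397 to 0.0946) and 0.0564% (0.0372 to 0.0854) of trans contacts, below the lowest WT library of each time (0.244% and 0.190%). Control probes gave a mean of 0.0321% at the same place over the libraries reported, which is not a like measure. It is a share of all their contacts off chromosome V, own chromosomes included, and some control probes lie on chromosome II with LYS2. The RE share was 0.953% at 2 h, below WT, and 0.374% at 4 h, within the WT range.

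Exo1 was removed (exo1D) or altered (labelled exo1-cd) to ask how resection sets the reach of ssDNA contacts. Distal probes stayed low at 4 h: per 10000 control contacts the 103.5 kb probe yielded 18.3 in exo1-cd and 16.3 in exo1D against 103 to 289 in WT, and the 130.8 kb probe 13.96 and 33.9 against 336 to 538. Trans shares at 2 h and 4 h were 51.9% and 53.4% in exo1-cd and 57.4% and 53.7% in exo1D, all below WT. This came from the left side, where the differences were −18.5 and −22.6 points in exo1-cd and −20.8 and −24.3 in exo1D. From right-side probes alone they were −2.99 and −0.840 in exo1-cd, and 8.29 and −0.0611 in exo1D. With 20 kb around the break left out the differences shrank, from −13.97 and −16.7 points to −5.90 and −9.71 in exo1-cd and from −8.48 and −16.4 to −3.46 and −11.4 in exo1D. With each pair counted once at equal depth they were −8.19 and −5.01 in exo1-cd and −4.98 and −7.25 in exo1D. At 2 h the left probe at 112.9 kb yielded little more than without a break, 12.1 in exo1-cd and 14.1 in exo1D against 10.4. The 115.9 kb probe was higher than without a break, at 88.6 and 72.8 against 45.2. The 116.5 kb probe was far higher, at 61.6 and 75.4 against 2.55. How far contacts not from ssDNA shape the shares at 2 h was not tested. Donor shares in exo1-cd were 0.440% (0.202 to 0.956) at 2 h, from 6 contacts and with an interval that holds both WT libraries, and 0.840% (0.618 to 1.14) at 4 h, above WT. The share was 0.388% (0.227 to 0.662) at 4 h in exo1D, within the WT range. At 2 h exo1D had 1 contact at the donor, below the floor of 3, and its interval (0.0113 to 0.361) held both WT libraries. The exo1-cd difference at 4 h was 0.774 points from left-side probes and −0.00346 from right-side probes. Pericentromeric enrichment at 2 h was 2.87 and 3.07, above both WT libraries, but left-side probes alone gave differences of −0.367 and −0.0404. At 4 h the values of 2.41 and 2.35 lay within the WT range, but the differences were −0.645 and −0.626 from left-side probes and 2.35 and 0.915 from right-side probes.

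Pol3 is the catalytic subunit of DNA polymerase delta and Rfc1 a subunit of the clamp loader, both used in DNA synthesis. Depleted libraries gave 79.8 (Pol3) and 90.8 (Pol3/Rfc1) ssDNA contacts per 100 control contacts, against 22.8 to 37.0 in WT at 4 h. Among the ssDNA probes, those far from the break rose most. Per 10000 control contacts the 126.7 kb probe, singled out after its values were seen, yielded 3275 and 3839 against 349 to 1031 in WT, the 103.5 kb probe 995 and 1218 against 103 to 289, and the 130.8 kb probe 1137 and 1435 against 336 to 538. The probes at 115.9, 117.0, 120.2, 121.7 and 121.9 kb stayed in the WT range in both. The rises were smaller in ppm of all library contacts, where most control probes lay below WT at 4 h. On that scale the 126.7 kb probe gave 3308 and 5186 against 858 to 2232 in WT. The 103.5 kb probe gave 1006 and 1645 against 338 to 626. The 130.8 kb probe gave 1149 with Pol3 depleted, within the WT range of 939 to 1773, and 1938 with Pol3/Rfc1 depleted. All other ssDNA probes lay within or below the WT range in both. Trans shares were 81.6% (81.4 to 81.9) and 81.3% (81.0 to 81.5), above every WT library. The differences from the WT mean, 11.5 and 11.2 points, were 7.03 and 7.09 with each pair counted once, and 5.68 and 5.16 with that at equal depth. Donor shares were 0.0866% (0.0685 to 0.110) and 0.0990% (0.0807 to 0.121), below every WT library. Pericentromeric enrichment was 2.87 and 2.38, or 1.57 and 1.54 with each pair counted once. From left-side probes the differences from WT were −0.781 and −0.814, and from right-side probes 0.725 and −0.404, so the pooled values mix sides that differ. The probe at 118.8 kb, next to the break and in no average of ssDNA probes, rose by a larger factor, to 506 and 338 against 5.74 to 9.68 in WT, and in both libraries yielded more than without a break.

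RE contacts were compared in strains with the element deleted or with 700 bp of it inserted on chromosome IV, at 2 h. The strain with the inserted copy had the highest share of contacts at the site: 92 fell within 5 kb of the site, 0.221% (0.180 to 0.271) of trans contacts, and no other library reported exceeded 0.0974%. The RE region on chromosome III in that library took 1.30% (1.19 to 1.41), between the WT libraries. The inserted and native copies were not told apart there. The trans share, 71.9%, was above both WT libraries, and 2.81 points above their mean with each pair counted once at equal depth. The donor share was above both too, by 0.0459 and 0.107 points, and pericentromeric enrichment by 0.0203 and 0.258. Right-side probes alone gave a donor difference of −0.0184 points, and left-side probes alone a pericentromeric difference of −0.458. Subtelomeric enrichment was below both. In the RE-deleted library the RE region took 0.0461% (0.0126 to 0.168), from 2 contacts, below the floor of 3 and in part because deleted fragments yield none, and chromosome III 4.44% (3.87 to 5.10), both below the WT libraries. HMR had 0 contacts within 5 kb and HML 0.0921%, against 1.09% and 0.389% (HMR) and 1.57% and 0.431% (HML) in WT. This library also had a trans share of 41.3% (40.4 to 42.3) and a pericentromeric enrichment of 9.21 (8.65 to 9.82), far outside the WT values, with 8.14 ssDNA contacts per 100 control contacts and a 118.8 kb yield above that without a break. Its difference in trans share from WT was −12.7 points from left probes and −43.7 points from right probes. The difference in pericentromeric enrichment was 6.31 from left probes and 14.7 from right probes.

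**Figure D3:**
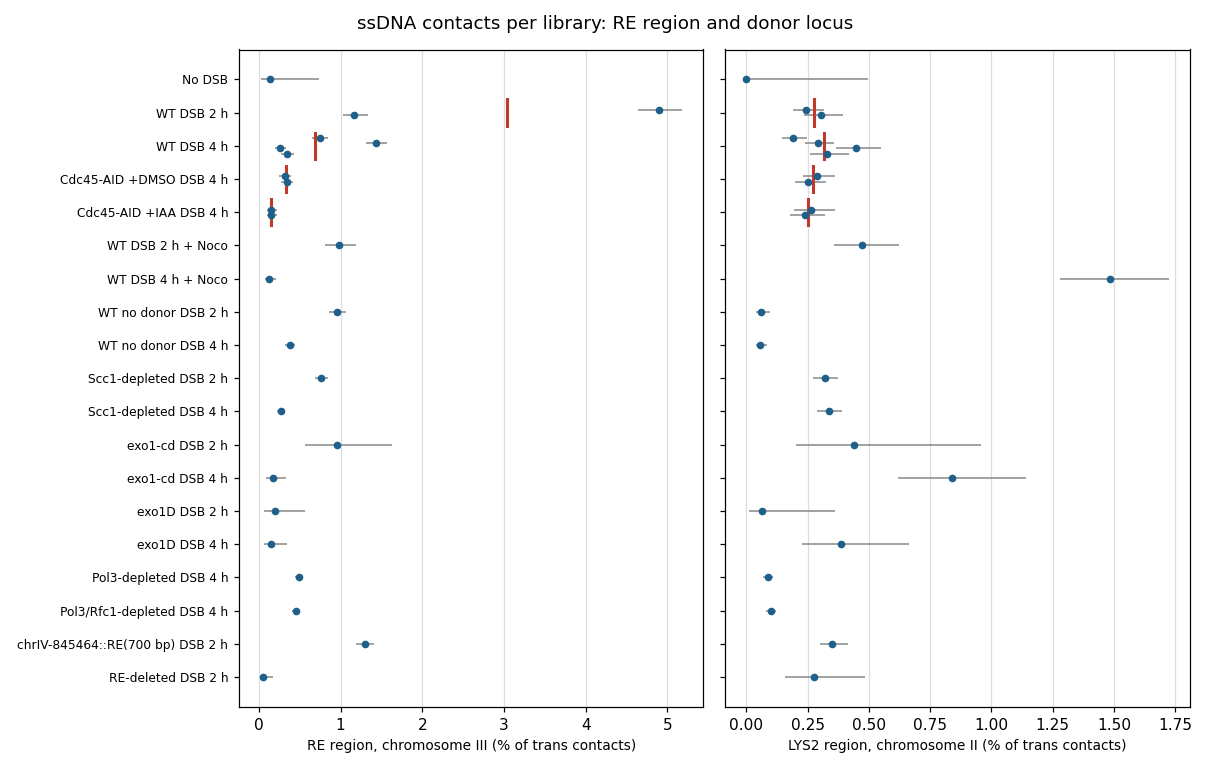
Share of trans contacts (percent) within 5 kb of the RE on chromosome III (left) and of LYS2 on chromosome II (right) per library (points, with 95% Wilson intervals) and group means (bars). The WT 2 h libraries reach 4.90% and 1.17% at the RE, and the RE-deleted library lies at 0.0461%.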

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

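All tests of explanations in this part were chosen only after the results were seen.

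The probe at 118.8 kb, next to the break, yielded more than in the No DSB library (55.1 per 10000 control contacts) in 3 of the 30 other libraries reported. These were RE-deleted (215), Pol3/Rfc1-depleted (338) and Pol3-depleted (506), and no other of those reported exceeded 16.2. Cells with an uncut site were not excluded. The probe at 114.4 kb was raised too, by at least 13.7 times its No DSB yield. Other probes lie between it and 118.8 kb, and its own rise is unexplained, so it cannot decide this. In RE-deleted the probe at 117.0 kb yielded 12.9 against 3.57 without a break, and that at 120.2 kb 11.2 against 15.4. The lower mapping tag alone is excluded, since 6 of the 9 libraries that carry it lay below No DSB. Among the libraries reported all 3 raised ones carried the lower tag and none of the 22 with the higher tag was raised, so a difference in library preparation within the lower tag stays open, and so do the genotypes of these single libraries, untested.

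The RE-deleted library combined a trans share of 41.3% with a pericentromeric enrichment of 9.21, at 2 h. Repeated pairs are excluded as the whole cause of the enrichment, which was 8.38 with each pair counted once and at most 2.46 in WT. They are excluded as the whole cause of the low trans share too. With each pair counted once and the WT libraries at 2 h drawn down to the same 10511 contacts (100 draws), its difference from the lowest WT library was −7.98 points, beyond the gap between the WT libraries (72.2% and 75.5%). A part in the trans share stays open, since its difference from the WT mean went from −24.6 to −9.60 points with pairs counted once at equal depth. The deletion of the RE was not tested as an explanation, as it has 1 library, and neither was a property of the library that comes with a high yield at 118.8 kb.

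Of 14 values tested for a library far from the others of WT at 4 h, the GAL2 share of replicate 1 (0.148%) stood apart, with a gap to the nearest library of 0.870 of the range, and chance gives such a gap in about 1 in 20 groups, so 1 among 14 values is about what chance gives.

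The other 7 of 8 probes that enter no average of ssDNA probes gave contacts above the No DSB library, here per 10000 control contacts and out of 30 libraries. The probe at 102.0 kb reached 372 in Pol3-depleted cells against 13.3 without a break and was above in 29 libraries. The probe at 108.4 kb reached 46.0 in Pol3-depleted cells against 4.60 and was above in 26. The probe at 112.2 kb reached 92.1 in Pol3/Rfc1-depleted cells against 2.04 and was above in 25. The probe at 114.4 kb reached 64.5 in Pol3-depleted cells against 1.76 and was above in 9. The probe at 128.1 kb reached 94.9 in Cdc45 IAA replicate 1 against 22.6 and was above in 21. The probe at 129.1 kb reached 6.79 in Cdc45 IAA replicate 2 against 1.02 and was above in 20. In Pol3-depleted cells the probe at 132.5 kb reached 66.2 against 12.8, and it was above in 13 libraries.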

How the results depend on the processing

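Most alternatives were chosen before the data were examined. Counting each fragment pair once, also at equal depth, and leaving chromosome III out of the subtelomeric measure and set, were chosen only after the data were seen. Among the 4 measures of the replicated comparisons, 118 values under an alternative kept their direction and 12 reversed. For conditions with 1 library 543 values stayed within 1 SD of the WT libraries from the planned value, 197 moved beyond it and 16 reversed, and all 14 values on annealing oligonucleotides stayed. Both planned window counts were 0, and of 33 counts under an alternative 23 were 0 and 10 were above 0. The cause of the changes below was not tested, except that side-specific probes and left-out libraries also leave fewer contacts.

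Window counts by edgeR were 0 for WT 4 h against 2 h and 0 for Cdc45. For WT they were 9 with TMM scaling, 6 with trans contacts as library size, 9 by DESeq2, 10 with left-side probes and 14 with each pair counted once. Without 1 library at a time they ran from 0 to 10 (WT) and 0 to 4 (Cdc45). The lone library left in an arm was then assumed to vary like the other groups. The donor share difference between WT times then ran from −0.00351 to 0.0821 points. Of 5 set test calls 2 held with an estimated correlation.

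With the replicate number as a block the donor share difference of WT 4 h and 2 h was −0.0332 points. The labels give replicates only a number, and the deviations from the group mean of libraries that share one had correlations of −0.251 (WT) and −0.0764 (Cdc45).

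For measures, values are differences of the first group named from the second, or of 1 library from WT at the same time, in percentage points for shares. Left-side probes gave a pericentromeric difference of −0.366 for WT 4 h against 2 h, −0.367 for exo1-cd and −0.0404 for exo1D at 2 h and −0.781 for Pol3. Their trans differences were 1.44 for Cdc45, −18.5 and −22.6 for exo1-cd at 2 h and 4 h, −20.8 and −24.3 for exo1D, 8.08 for Pol3, 5.69 for Pol3/Rfc1, 9.85 for the chromosome IV RE strain and −12.7 for RE-deleted. The donor difference was 0.0275 for Cdc45 and the subtelomeric difference 0.00684 for exo1D at 4 h.

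Right-side probes gave donor differences of −0.0619 for WT 4 h against 2 h, −0.0231 for Scc1-depleted at 2 h, −0.00346 for exo1-cd at 4 h and −0.0184 for the chromosome IV RE strain. Their trans differences were −2.99 and −0.840 for exo1-cd at 2 h and 4 h, 8.29 and −0.0611 for exo1D, −7.22 for Noco at 2 h, −2.13 for no donor at 2 h, 14.96 for Pol3, 15.7 for Pol3/Rfc1 and −43.7 for RE-deleted.

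With each pair counted once the pericentromeric difference was −0.607 for Pol3 and the donor difference 0.00826 for Cdc45. The trans difference was 7.88 and 3.70 for Scc1-depleted at 2 h and 4 h, −17.7 and −10.2 for exo1-cd, −14.3 and −13.5 for exo1D, 7.03 for Pol3, 7.09 for Pol3/Rfc1 and −14.5 for RE-deleted. These mix repeats with depth. With each pair counted once at equal depth it was 7.01 and 3.13 for Scc1-depleted at 2 h and 4 h, −8.19 and −5.01 for exo1-cd, −7.25 for exo1D at 4 h, 5.68 for Pol3, 5.16 for Pol3/Rfc1 and −9.60 for RE-deleted.

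With 20 kb around the break left out the trans difference was 5.97 for Scc1-depleted at 4 h, −5.90 and −9.71 for exo1-cd at 2 h and 4 h, −3.46 and −11.4 for exo1D, 8.58 for Pol3, 7.87 for Pol3/Rfc1 and −16.7 for RE-deleted. With 5 kb left out it was −18.0 and −22.6 for exo1-cd at 2 h and 4 h, and −12.7 and −21.2 for exo1D.

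With the mean of per-probe values the pericentromeric difference was −0.0579 for WT 4 h against 2 h and −0.268 for Pol3, and the donor difference 0.129 for exo1D at 2 h. The trans difference was −8.20 for exo1-cd at 2 h, −3.73 and −12.9 for exo1D at 2 h and 4 h, and −13.0 for RE-deleted.

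Divided by the control-probe value, the donor difference was −0.00164 for WT 4 h against 2 h, −0.0988 for Scc1-depleted at 2 h and −0.000513 for Noco at 2 h, and the pericentromeric difference 0.481 for no donor at 2 h. The control-probe value includes contacts of control probes with their own chromosomes, so it is not a like measure. With 40 kb flanks the pericentromeric difference was −0.0821 for WT 4 h against 2 h. With a 10 kb donor flank the donor difference was 0.00430 for Cdc45, and with 2 kb 0.0149 for Cdc45 and −0.00649 for the chromosome IV RE strain.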

Other observations

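All comparisons in this part were chosen only after the values were seen, and none was tested between single libraries. Contacts with GAL1-GAL10-GAL7 on chromosome II took 0.0841% (Wilson interval 0.0663 to 0.107) of trans contacts in Pol3-depleted cells and 0.0699% (0.0549 to 0.0891) in Pol3/Rfc1-depleted cells, below the 4 WT libraries at 4 h (0.214% to 0.395%). The share was also below that range in exo1-cd at 4 h (0.126%) and in both Cdc45 IAA libraries (0.146% and 0.102%). The GAL1-GAL10-GAL7 share was 0.668% (0.465 to 0.958) in the RE-deleted library, above both WT libraries at 2 h (0.253% and 0.326%).

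The rDNA on chromosome XII took 2.65% (2.16 to 3.25) of trans contacts in exo1D at 4 h, 1.47% (1.17 to 1.85) in exo1-cd at 4 h and 1.81% (1.72 to 1.90) in Pol3/Rfc1-depleted cells, above the 4 WT libraries at 4 h (0.263% to 0.792%). Other libraries at 4 h exceeded the WT range by less, among them 1 of 2 Cdc45 DMSO controls (1.17%), both Cdc45 IAA libraries (1.01% and 1.04%), Noco (0.826%) and no donor (0.823%). In Pol3-depleted cells the rDNA share was 0.566% (0.516 to 0.621), within the WT range.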
